A study of Mus musculus with 66 samples.

How the data were processed

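RNA was measured in pyramidal neurons of hippocampal field CA1 cut out by laser from 20 µm sections of female mice aged about 11 months. Ts2 mice carry 3 copies of parts of mouse chromosomes 16 and 17, joined to chromosome 12 as a translocation, and serve as a model of Down syndrome. Their 2N littermates carry 2 copies. Each of the 22 mice, 11 per genotype, gave 3 captures: the whole pyramidal layer of rostral CA1 (about 500 to 600 neurons), and the deep and the superficial sublayer of distal CA1 (about 500 to 1500 cells each). Batch 1 held 6 mice of each genotype and batch 2 held 5. Per the labels' protocols, batch 2 took all captures from neighbouring sections of a slide, while batch 1 took the sublayers from slides next to the one used for the whole layer. Neurons were chosen by their position in the tissue.

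The 66 libraries were made with a stranded total RNA kit for very small amounts of RNA and read for 50 cycles from 1 end, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.39, STAR, RSEM and the builds GRCm39 and mm10, without saying which step used which build. Per the file headers, each deposited gene table gives RSEM expected counts with effective lengths, TPM and FPKM. The expected counts that the authors deposited are estimated counts that need not be whole numbers, and they carry no scaling for depth. Tables of the whole series held the same values, so only the tables per sample were used, and TPM and FPKM were not used. The gap between stated and effective gene lengths implies fragments of 50 bases in all batch 1 libraries and of 175.8 to 257.5 bases in batch 2, so the batches differ in sequencing, library or processing, and which of these was not tested. All tests between genotypes therefore compared mice within batches.

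Gene symbols, chromosomes and gene order came from a GENCODE annotation of the older GRCm38 build, matched by gene identifier. It named 52081 of 55414 identifiers (94.0%). No positions are printed, because the build behind the counts was not settled. The trisomic segments were taken as the genes on chromosome 16 from Mrpl39 onward and those on chromosome 17 up to Pde10a.

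Total counts per library ran from 0.74 to 38.45 M with a median of 16.93 M. The median was 19.73 M in batch 1 and 11.97 M in batch 2. These depths set the counting error only. Beyond counting error, libraries had a biological coefficient of variation of 0.565 in the whole layer, 0.618 in the deep sublayer and 0.647 in the superficial sublayer. With 1 library per mouse and capture, it holds differences between mice together with those between captured samples and libraries. With the mouse as a block, the fit of deep against superficial still gave 0.63.

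Expected counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, a minimum count of 10 in edgeR's expression filter, robust dispersion estimation and Benjamini-Hochberg adjustment at 0.05. Genotypes were compared within each capture over 22 libraries with batch as a term. The deep and superficial sublayers were compared within mice, with the mouse as a block, and so were the tests of whether the genotype effect differed between captures. The mouse pairs the captures by design. As a check, deviations from the median of each capture and batch were taken over 300 genes that varied together across captures in the other batch. Between the deep and superficial libraries of a mouse they correlated above 0.1 in 12 of 12 mice of batch 1. In batch 2 this held in 9 of 9 mice. Between the deep sublayer and the whole layer this held in 8 of 12 and 10 of 10 mice. Between the superficial sublayer and the whole layer it held in 7 of 12 and 10 of 10. The 9 mice include 16-207 and 16-208, whose superficial libraries went against their genotype, so a correlation above 0.1 cannot settle the pairing. By a stricter measure, 5 of 12 whole-layer, 9 of 12 deep and 9 of 12 superficial libraries of batch 1 correlated best with their own mouse. In batch 2 it was 9 of 10 in each capture.

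The deep and superficial files of 2N mouse 15-50 held identical values in 55414 of 55414 genes. Which sublayer they come from cannot be read from them, so this mouse was left out of the comparison of the sublayers and kept in the genotype tests and in comparisons with the whole layer. Further doubted libraries were 5 with fewer than 16000 detected genes, namely the whole layer of 2N mouse 16-268, the deep sublayer of 2N mouse 16-268 and Ts2 mouse 16-319, and the superficial sublayer of Ts2 mice 16-267 and 16-319. The superficial libraries labelled as Ts2 mouse 16-207 and 2N mouse 16-208 went against their genotype. All of these stayed in the main tests and were left out in alternatives chosen after seeing the data.

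A dosage value per library was computed from trisomic genes with a mean log2 CPM of at least 4, as their median log2 ratio to the 2N median minus that of all other genes. Single values were compared with two-sided permutation tests, of 100000 resamples with 10 or more libraries per group and exact otherwise. CPM values use TMM-scaled library sizes.

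Gene lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and fry served as alternatives. The 33 lists were the genes of each trisomic segment, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, glutamate receptors, the GABA system, postsynaptic scaffolds, presynaptic vesicle genes, calcium and calmodulin signalling, potassium channels, MAPK, PI3K and mTOR signalling, the ubiquitin-proteasome system, chaperones, endosome, lysosome and autophagy genes, Alzheimer-related genes, neurotrophin and cholinergic genes, immediate early genes, cytoskeleton and axon genes, the interferon response, and markers of superficial CA1, deep CA1, CA1 pyramidal, CA3 and CA2, dentate, interneuron, astrocyte, microglia, oligodendrocyte, oligodendrocyte precursor, endothelial and pericyte, choroid and ependymal, and blood cells. The last 2 had too few tested members for camera and were followed only as marker scores, the mean log2 CPM of a list in a library.

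The tests, covariates, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each genotype comparison, the 10 genes outside the trisomic segments that rose and the 10 that fell with the smallest adjusted p under 0.05, filled up to 5 with the smallest p where fewer passed. It also took up to 4 members of each list with the smallest p, up to 10 genes called in all 3 captures, the 10 smallest p in each direction between the sublayers and 5 for each test of a differing genotype effect, leaving out unnamed gene models, and a fixed set of genes reported whatever their values. The count step was tested on simulated data with 200 changed genes. With 22 libraries per capture it recovered 6.25% of genes changed 1.5-fold and 22.7% of those changed 2-fold in the whole layer, 18.1% and 47.4% in the deep sublayer, and 12.4% and 43.3% in the superficial sublayer, with 1 or 2 unchanged genes called. Between the sublayers it recovered 36.2% and 57.1%, and for a differing genotype effect 6.25% and 26.1%.

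Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, other scalings, no filter or a mean CPM of at least 5, no batch term, each batch alone, protein-coding genes only, a surrogate variable, all 66 libraries in a single fit, unrounded counts, a threshold of 0.1, no mouse block, and leaving out each mouse. Expected counts split reads between near-identical genes, so values of ribosomal protein, tubulin, calmodulin and heat shock protein genes with pseudogene copies are uncertain. Whether the counting used the strand is not given in the sources used here, so antisense genes were not singled out.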

Results

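Gene expression was measured in 66 libraries from laser-captured CA1 pyramidal neurons of 22 female mice, 11 Ts2 and 11 2N. Each mouse gave a whole-layer, a deep and a superficial library. The median total count was 25.0 M in the 11 whole-layer 2N libraries and 26.67 M in the 11 of Ts2. It was 15.58 M in the deep 2N libraries and 15.26 M in those of Ts2. In the superficial sublayer it was 10.8 M in 2N and 11.46 M in Ts2. A library had a median of 19727 detected genes, with a range of 6344 to 26582. The lowest value belonged to the whole layer of 2N mouse 16-268, which had 0.74 M counts. The deep and superficial files of 2N mouse 15-50 were identical, and this mouse was left out where the sublayers are compared.

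The genotype labels were checked first, through the genes that Ts2 mice carry in 3 copies. The trisomic dosage, a log2 ratio that 3 copies against 2 would put near 0.585, was 0.55 ± 0.04 (SD, n = 11) in the deep sublayer of Ts2 mice and 0.01 ± 0.07 (SD, n = 11) in 2N mice (permutation test, two-sided, p = 2e-05). All 11 deep Ts2 libraries lay above the highest 2N library. In the whole layer the dosage was 0.53 ± 0.04 (SD, n = 11) in Ts2 against 0.07 ± 0.24 (SD, n = 11) in 2N (permutation p = 8e-05). The value of 0.774 in the whole layer of 2N mouse 16-268 rests on few detected genes. In the superficial sublayer the dosage was 0.47 ± 0.16 (SD, n = 11) against 0.04 ± 0.20 (SD, n = 11; permutation p = 0.00033). There the library labelled as Ts2 mouse 16-207 had a dosage of 0.051, and the library labelled as 2N mouse 16-208 had 0.563.

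**Figure D1:**
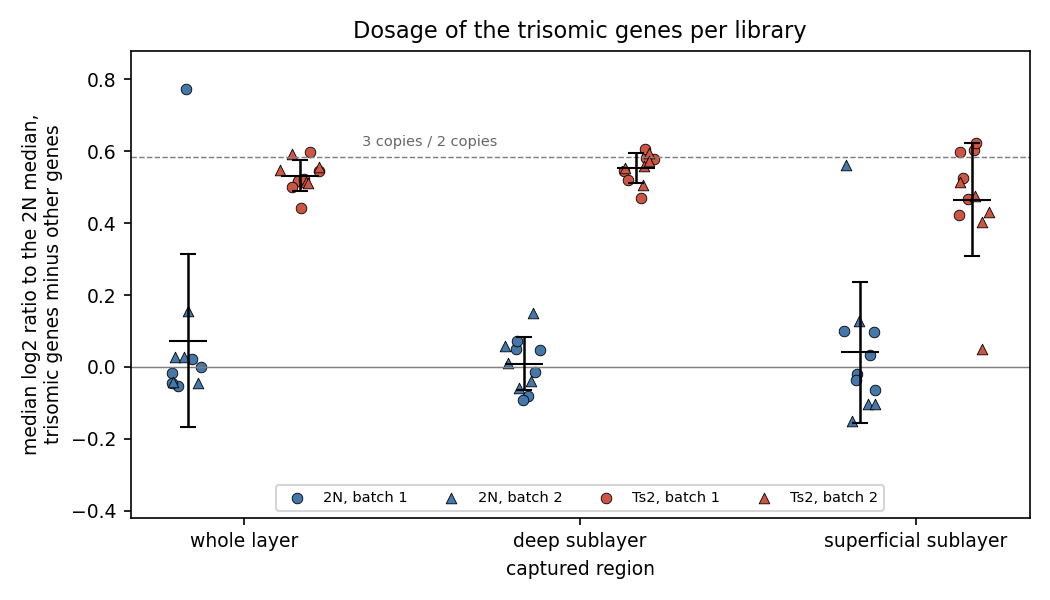
Trisomic dosage per library (median log2 ratio to the 2N median, trisomic genes minus all other genes) for the 3 captures, by genotype and batch, with the mean and SD of each group of 11. The dashed line marks 3 copies against 2, and a superficial library of each genotype, 0.051 in Ts2 and 0.563 in 2N, lies at the level of the other genotype.

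The first comparison asks how far the extra gene copies are expressed in these neurons. Trisomic genes were expressed at close to 1.5 times the 2N level in the whole layer and the deep sublayer. Their median fold was 1.466 over 123 tested genes in the whole layer, 1.46 over 117 in the deep sublayer and 1.337 over 112 in the superficial sublayer. Expression was higher in Ts2 for 110 of the 123 genes, 109 of the 117 and 103 of the 112. The chromosome 16 part had a median log2 difference of 0.55 in the whole layer, 0.50 in the deep and 0.44 in the superficial sublayer, and the chromosome 17 part had 0.53, 0.60 and 0.41. Genes elsewhere on these chromosomes stayed near 1, with median folds between 0.98 and 1.026. Genes of chromosome 12, which holds the translocation, had median folds of 0.987, 0.979 and 0.996 in the 3 captures.

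By edgeR's test over all genes, 1 trisomic gene rose in the whole layer, 17 in the deep sublayer and 3 in the superficial sublayer. Adjusted over the list alone, these counts were 33, 49 and 35. Camera called both segments higher in every capture, and every such call held with an estimated correlation. The largest of those adjusted p was 7.4e-04, for the chromosome 17 segment in the superficial sublayer. Leaving out the doubted libraries, an alternative chosen after seeing the data, gave 18, 18 and 10 trisomic genes over all genes and 67, 57 and 45 adjusted over the list alone. The superficial median log2 difference was then 0.52.

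In the deep sublayer App, the amyloid precursor protein, rose by a log2 fold change of 0.62 ± 0.08 (SE), from 2103 ± 507 CPM (SD, n = 11) in 2N to 3172 ± 376 CPM (SD, n = 11) in Ts2 (edgeR, adjusted p = 0.00013). Synj1, a phosphoinositide phosphatase of synaptic vesicle recycling, rose by 0.70 ± 0.08 (SE, adjusted p = 1.8e-05), and Ttc3, an E3 ubiquitin ligase, by 0.58 ± 0.07 (SE, adjusted p = 1.8e-05). Son, a nuclear speckle protein of RNA splicing, rose by 0.57, Sod1, the cytosolic superoxide dismutase, by 0.67, and Kcnj6, an inwardly rectifying potassium channel, by 0.52. The kinase Dyrk1a rose by 0.72 ± 0.13 (SE, adjusted p = 0.0049) and Itsn1, a scaffold of endocytosis, by 0.68. The other trisomic genes that rose there were Tulp4 (0.82), Dop1b (0.74), Tmem50b (0.69), Gart (0.90), Scaf8 (0.48), B3galt5 (0.81), Synj2 (0.59), Ifngr2 (0.78) and Cct8 (0.57). Of these 17 genes, 16 were above the 2N mean of their batch in 11 of 11 Ts2 libraries, and Cct8 was so in 10.

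Other trisomic genes of interest did not pass over all genes. Rcan1, a regulator of calcineurin, had a log2 difference of 0.79 in the whole layer, 0.67 in the deep and 0.61 in the superficial sublayer, and it passed in each when adjusted over the list alone (adjusted p = 0.021, 0.0027 and 0.0094). Hmgn1, a nucleosome-binding protein, had 0.50, 0.40 and 0.59, and passed over the list alone in the superficial sublayer (adjusted p = 0.0057). The chromatin remodeller Arid1b had 0.16, 0.55 and 0.42, and passed over the list alone in the deep (adjusted p = 0.0011) and superficial sublayer (adjusted p = 0.010). Without the doubted libraries Arid1b passed over all genes in the superficial sublayer (adjusted p = 0.00074). Pcp4, a calmodulin-binding protein, had 0.88, 0.72 and 0.28 with standard errors of 0.87, 0.76 and 0.85. Pde10a, at the boundary of the segment, had 0.29, 0.32 and 0.29. Olig2, an oligodendrocyte-lineage factor, had 1.17, -0.03 and 0.23.

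**Figure D2:**
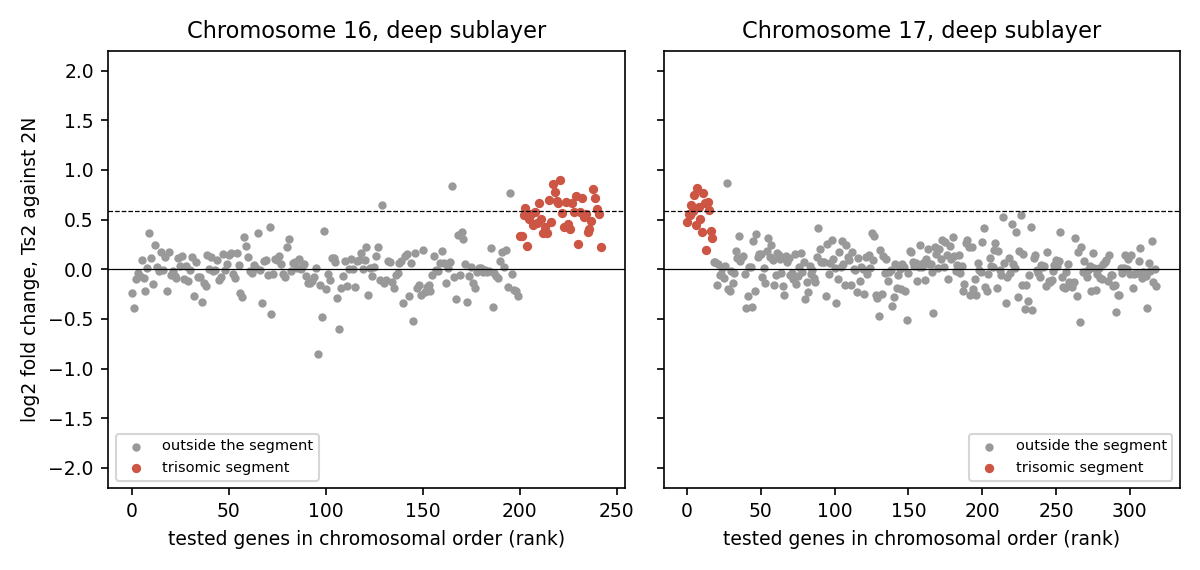
Log2 fold change of Ts2 against 2N in the deep sublayer for tested genes with a mean log2 CPM of 4 or more, in their order along chromosome 16 (243 genes, 43 in the segment) and chromosome 17 (319 genes, 18 in the segment). The genes of both segments lie around the dashed line at 1.5-fold, and the other genes lie around 0.

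The next comparison asks which genes outside the segments differ between genotypes in each capture. In the deep sublayer 2 named genes rose and 1 fell. Col4a1, a chain of basement membrane collagen, rose by 0.83 ± 0.17 (SE), from 63.3 ± 23.5 CPM (SD, n = 11) to 112.6 ± 31.0 CPM (SD, n = 11; adjusted p = 0.024). Phldb1, a protein with a pleckstrin homology-like domain, rose by 1.02 ± 0.19 (SE, adjusted p = 0.014). Rfx5, a transcription factor of MHC class II genes, fell from 17.6 ± 8.4 CPM (SD, n = 11) to 6.59 ± 2.66 CPM (SD, n = 11), a log2 change of -1.39 ± 0.29 (SE, adjusted p = 0.035). Both genes that rose were above the 2N mean of their batch in 11 of 11 Ts2 libraries, and Rfx5 was above it in 0 of 11. The pseudogene Gm34583, named after its value was seen, also fell (-0.70, adjusted p = 0.031). The genes next in rank did not pass: Hpcal4, a neuronal calcium sensor, had 0.58 (adjusted p = 0.078), the LIF receptor Lifr 0.72 (0.082) and the prostaglandin D synthase Ptgds 1.13 (0.10). On the lower side were the actin crosslinker Flna with -0.60 (0.078), Nap1l5 with -0.59 (0.086), the T-type calcium channel Cacna1g with -1.13 (0.14) and the small GTPase Arl4a with -0.60 (0.16). In all, edgeR called 21 of 14959 genes, 19 higher and 2 lower in Ts2. At an unadjusted p under 0.05 there were 712 genes, where chance gives about 748.

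In the whole layer Synj1 was the only call among 16522 genes. It rose from 591 ± 126 CPM (SD, n = 11) to 1022 ± 105 CPM (SD, n = 11), a log2 change of 0.79 ± 0.13 (SE, edgeR adjusted p = 0.028). Outside the segments no gene passed by edgeR, while 675 had an unadjusted p under 0.05 against 820 by chance. Closest on the lower side was the mitochondrial uncoupling protein Ucp2, with 15.3 ± 12.6 CPM (SD, n = 11) in 2N and 2.80 ± 2.04 CPM (SD, n = 11) in Ts2 (log2 -2.51, adjusted p = 0.12). It was followed by Flna (-0.72), the imprinted gene Zdbf2 (-0.84), the axonal adhesion molecule Cntn4 (-1.13) and Rfx5 (-0.86). On the higher side were the growth factor binding protein Igfbp2 (2.29, adjusted p = 0.33), Mettl26 (1.10), the myelin-associated glycoprotein Mag (1.44), the cytokine Il34 (1.06) and the focal adhesion protein Parva (0.90). Without the low library of 2N mouse 16-268 the count was 25, with 18 trisomic genes. The others were Ucp2 (-2.61, adjusted p = 0.011), Rfx5 (-0.93, 0.036) and Flna (-0.74, 0.036), which fell, and the axonal guidance protein Dpysl3 (0.72, 0.042), Mettl26 (1.06, 0.042), Parva (0.84, 0.048) and a gene without a symbol, which rose. DESeq2 called 40 genes with all libraries and limma-voom with quality weights called 99. The Synj1 call ended without any one of 2N mice 15-223, 15-49, 15-71 and 16-04 or Ts2 mice 15-224, 15-51, 15-72, 15-70, 16-178, 16-267, 16-177, 16-207, 16-154 and 16-179, and the count was 2 without 2N mouse 16-189 or 16-208 or Ts2 mouse 16-319.

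In the superficial sublayer all 3 calls among 13956 genes were trisomic. Son rose by 0.55 ± 0.09 (SE), from 603 ± 93 CPM (SD, n = 11) to 887 ± 113 CPM (SD, n = 11; edgeR adjusted p = 0.0052). Ttc3 rose by 0.54 ± 0.09 (SE, adjusted p = 0.0052) and Synj1 by 0.55 ± 0.10 (SE, adjusted p = 0.029). Outside the segments no gene passed by edgeR, and 452 had an unadjusted p under 0.05 against 692 by chance. The chance value assumes evenly spread p. Counts below it, here and in the whole layer, mean that p ran large, so absent calls are weak evidence of no change. Closest were Col4a1 (0.76, adjusted p = 0.20), the scaffold Magi3 (0.76), the kinase Pak1 (0.33), the RNA export factor Nxt2 (0.83) and the proteasome subunit Psmd12 (0.55) on the higher side. The matrix protein Spon1 (-0.52, adjusted p = 0.58), the phosphatase methylesterase Ppme1 (-0.29), the circadian receptor Nr1d2 (-0.52), Ucp2 (-2.52) and the GABA-B receptor subunit Kctd12 (-0.38) led the lower side. Without the library labelled as Ts2 mouse 16-207 the count was 10, and without that labelled as 2N mouse 16-208 it was 9. Without all doubted libraries it was 11, and Col4a1 then rose by 0.96 ± 0.16 (SE, adjusted p = 0.0045). DESeq2 called 11 genes and limma-voom with quality weights 28.

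Genes fixed in advance outside the segments did not pass between genotypes over all genes by edgeR in any capture. Calb1, the calbindin of superficial CA1 neurons, had log2 differences of -1.03 in the whole layer, -0.65 in the deep and -0.80 in the superficial sublayer. Ndst4, a heparan sulfate enzyme and marker of deep CA1, had -1.12, -0.69 and -0.43. Adjusted over the list of deep CA1 markers alone, Ndst4 and Col11a1 (-0.89) fell in the whole layer, where the other 2 of 4 members were higher. The neurotrophin Bdnf had 0.08, -0.09 and 0.05, its receptor Ntrk2 had -0.08, -0.10 and -0.09, and the kinase Camk2a had 0.22, 0.14 and 0.14.

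Gene groups were compared between genotypes in the same captures. Oligodendrocyte markers were higher in Ts2 in the deep sublayer for 15 of 16 tested members, with a median log2 difference of 0.42 (camera adjusted p = 8.4e-08). This was the only call outside the segments that held with an estimated correlation (adjusted p = 0.043 with an estimated correlation), and fry gave 0.026. No member passed over all genes and 1 rose adjusted over the list alone. The members with the smallest p were the myelin genes Mag (0.95), Mbp (0.34), Mal (0.74) and Cnp (0.58). Marker scores, the mean log2 CPM per library, were 3.73 ± 0.32 (SD, n = 11) in deep Ts2 libraries and 3.06 ± 0.59 (SD, n = 11) in deep 2N libraries (permutation p = 0.0021, adjusted over 33 genotype tests of scores to 0.069). Within batches the difference was 0.929 in batch 1 (exact permutation p = 0.0065) and 0.367 in batch 2 (exact permutation p = 0.21). In the whole layer oligodendrocyte markers were higher in 14 of 16 members (camera adjusted p = 6.5e-06, and adjusted p = 0.31 with an estimated correlation), and in the superficial sublayer in 14 of 15 (camera adjusted p = 0.0071, and adjusted p = 0.65 with an estimated correlation). The superficial call ended without the doubted libraries (camera adjusted p = 0.20) and in batch 2 alone (0.76).

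**Figure D3:**
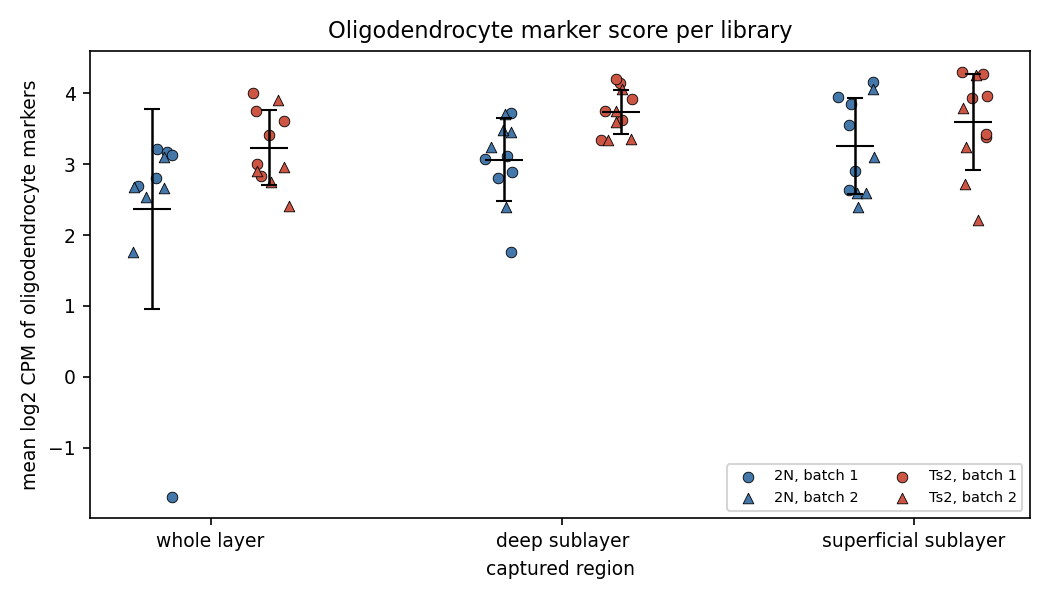
Oligodendrocyte marker score (mean log2 CPM of the list) per library for the 3 captures, by genotype and batch, with the mean and SD of each group of 11. In the deep sublayer Ts2 libraries average 3.73 and 2N libraries 3.06; the lowest whole-layer point is the shallow library of 2N mouse 16-268.

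Presynaptic vesicle genes were higher in Ts2 in all 3 captures by camera, for 36 of 44 members in the whole layer (adjusted p = 4.9e-09), 38 of 44 in the deep sublayer (1.1e-05) and 33 of 44 in the superficial sublayer (0.0010). With an estimated correlation the adjusted p were 0.27, 0.42 and 0.65. Synj1, which is trisomic, was the only member that passed in each capture, over all genes and over the list alone. Snap91, an adaptor of clathrin coats, had 0.40 in the whole layer, and Ap2a1, of the endocytic adaptor complex, had 0.31 in the deep sublayer. Cytoskeleton and axon genes were higher by camera for 28 of 40 members in the whole layer, 30 in the deep and 30 in the superficial sublayer (adjusted p = 4.9e-09, 8.4e-04 and 0.019). With an estimated correlation these were adjusted p = 0.27, 0.53 and 0.65. Without the doubted libraries the superficial calls of both lists ended, with camera adjusted p = 0.062 for presynaptic vesicle and 0.14 for cytoskeleton and axon genes. They also ended in batch 2 alone (0.90 and 0.50), and the deep cytoskeleton call ended in batch 1 alone (0.22). No member of the latter passed over all genes. In the deep sublayer 3 rose adjusted over the list alone, the tubulins Tuba1a (0.50), Tubb4a (0.37) and Tubb2b (0.64).

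Cytosolic ribosomal proteins were lower in Ts2 by camera in the whole layer, with 25 of 78 members higher (adjusted p = 0.024), and in the deep sublayer, with 12 of 78 higher (adjusted p = 2.8e-06). With an estimated correlation these were adjusted p = 0.78 and 0.53. Nuclear genes of oxidative phosphorylation were lower in the deep sublayer, with 12 of 75 higher (adjusted p = 1.5e-04, and adjusted p = 0.71 with an estimated correlation). By camera the deep ribosomal call passed in batch 1 alone (adjusted p = 4.8e-10) and not in batch 2 alone (0.51), and the deep oxidative phosphorylation call likewise (2.1e-05 and 0.36). The whole-layer ribosomal call passed in batch 2 alone (1.0e-05) and not in batch 1 alone (0.74). In the whole layer, genes of oxidative phosphorylation were higher in batch 1 by camera (0.0029) and lower in batch 2 (3.3e-05), with 36 of 75 members higher over all mice (0.77). Interneuron markers were lower in the deep sublayer, with 3 of 16 higher (adjusted p = 2.0e-05, and adjusted p = 0.16 with an estimated correlation). Gad2, a GABA-synthesizing enzyme, had -0.43 and the peptide Sst had -0.85. The interneuron score was 5.02 ± 0.49 (SD, n = 11) in Ts2 and 5.33 ± 0.29 (SD, n = 11) in 2N there (permutation p = 0.055). Immediate early genes were lower in the deep sublayer, with 3 of 22 higher (adjusted p = 0.026, and adjusted p = 0.57 with an estimated correlation), among them Npas4 with -0.83 and Nr4a2 with -0.62, and the call ended in batch 2 alone (0.13). No member of these 4 lists passed over all genes or adjusted over the list alone.

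Smaller calls by camera were Alzheimer-related genes (whole layer adjusted p = 0.013, deep 0.026), the interferon response (deep 0.039, superficial 0.036) and oligodendrocyte precursor markers (whole layer 0.027), all higher in Ts2. With an estimated correlation the adjusted p were 0.72 and 0.13, 0.32 and 0.29, and 0.56. These lists hold the trisomic genes App, Dyrk1a and Bace2, Ifngr2, Ifnar1 and Ifnar2, and Olig1 and Olig2, and without trisomic members camera gave adjusted p = 0.085 and 0.39, 0.76 and 0.74, and 0.56. In batch 2 alone the whole-layer Alzheimer-related (0.13), superficial interferon (0.80) and precursor (0.056) calls ended, and in batch 1 alone the deep Alzheimer-related (0.31) and interferon (0.28) calls did. MAPK, PI3K and mTOR genes (0.024), endosome, lysosome and autophagy genes (0.030) and CA3 and CA2 markers (0.030) were higher in the whole layer, each with adjusted p = 0.78 with an estimated correlation. Without trisomic members the first and last no longer passed (camera adjusted p = 0.057 and 0.085), and without the doubted libraries the first did not (0.17). None of these 3 passed in batch 2 alone by camera (0.23, 0.94 and 0.55). Mitochondrially encoded genes were higher in the superficial sublayer (0.019, and adjusted p = 0.81 with an estimated correlation), a call that ended without the doubted libraries (0.83) and in batch 2 alone (0.14).

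The remaining lists passed in no capture. The lowest camera adjusted p were 0.53 for glutamate receptors, 0.35 for the GABA system, 0.29 for postsynaptic scaffolds, 0.20 for calcium and calmodulin signalling, 0.12 for potassium channels, 0.095 for the ubiquitin-proteasome system, 0.30 for chaperones and 0.20 for neurotrophin and cholinergic genes. Among markers they were 0.16 for superficial CA1, 0.54 for deep CA1, 0.84 for CA1 pyramidal, 0.76 for dentate, 0.35 for astrocyte, 0.63 for microglia and 0.42 for endothelial and pericyte cells. The scores of choroid and ependymal markers differed by 0.262 in the deep sublayer (permutation adjusted p = 0.93), and that of blood, a single gene, by 1.091 (permutation adjusted p = 0.11).

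A further question was whether the captures share genotype effects. Synj1 rose in all 3 captures and was the only gene to do so, where 7 genes did without the doubted libraries. All 3 genes that rose in the superficial sublayer, each of them trisomic, also rose in the deep sublayer of the same mice. Outside the segments the log2 differences correlated weakly across genes between captures. Pearson's r was 0.124 for deep and superficial, 0.172 for deep and whole and 0.104 for superficial and whole, with covariances of 0.019, 0.029 and 0.017. Genotype labels permuted over mice gave median r of 0.116, 0.097 and 0.074 and median covariances of 0.018, 0.015 and 0.011 (genes are not independent replicates). The deep and superficial tests both hold the identical file of 2N mouse 15-50. Part of what these 2 captures share therefore follows from that file, under real and permuted labels alike.

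Whether the genotype effect differs between captures was tested directly, and no gene passed by edgeR. Between the deep and superficial sublayers 489 of 15128 genes had an unadjusted p under 0.05, against 756 by chance. Between deep and whole there were 193 against 800, and between superficial and whole 245 against 789. These chance values assume evenly spread p. All 3 counts lie well below them, so p ran large in these tests, and a count of 0 is weak evidence of no difference. Why p ran large was not tested. The smallest p for a higher Ts2 effect in deep than in superficial belonged to Klhl2 (difference of 0.50), the microtubule protein Mapt (0.40), Fnbp1 (0.59), Fam234b (0.55) and Prpf40b (0.53). For a lower effect they belonged to Tspan13 (-0.40), Sowaha (-0.65), Aatf (-1.09), Cox5b (-0.49) and Katnal1 (-0.64). Among named genes, deep against whole was led by Myl6b (1.37), Pstk (0.79), Oxld1 (1.82), Snhg14 (0.31) and Med12 (0.64) and by Ubl3 (-0.54), Fzd9 (-4.87), Smox (-1.06), Mctp1 (-0.99) and Pdlim5 (-1.04). Superficial against whole was led by Rpl22l1 (1.47), Serpini1 (0.48), Zfp39 (0.86), Utp6 (0.72) and Snhg11 (0.48) and by Fam114a1 (-5.04), Pcdhga1 (-1.44), Olig1 (-1.76), Nectin4 (-2.29) and Mettl26 (-1.26). Without a mouse block edgeR also called 0 genes in each of the 3 tests. Of genes changed 2-fold in simulated data, 26.1% were recovered by the deep against superficial test. Recovery was not simulated for the tests against the whole layer, which include the library of 0.74 M counts.

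The last comparison asks how deep and superficial CA1 neurons differ within the same mice. Sparcl1, a secreted protein of synapse formation, was higher in the deep sublayer of 21 of 21 mice, at 944 ± 318 CPM (SD, n = 21) against 690 ± 239 CPM (SD, n = 21), a log2 difference of 0.46 ± 0.05 (SE, edgeR adjusted p = 1.3e-06). Ank3, which encodes ankyrin-G of the axon initial segment, was higher by 0.33 ± 0.04 (SE, 21 of 21 mice, adjusted p = 2.3e-06). Cnr1, the cannabinoid receptor and a member of the interneuron list, was lower in the deep sublayer of 21 mice. It had 109 ± 31 CPM (SD, n = 21) against 161 ± 57 CPM (SD, n = 21), a log2 difference of -0.53 ± 0.09 (SE, edgeR adjusted p = 0.0010). Kcnq3, a subunit of the M-current potassium channel, was lower by -0.34 ± 0.05 (SE, higher in 1 of 21 mice, adjusted p = 0.00013). The fixed sublayer markers Ndst4 (1.19 ± 0.28 SE, higher in 18 of 21 mice, adjusted p = 0.034) and Col11a1 (0.95 ± 0.13 SE, 20 of 21 mice, adjusted p = 0.00034) were higher in the deep sublayer, while Calb1 had -1.19 ± 0.35 (SE, higher in 2 of 21 mice) and did not pass (adjusted p = 0.10).

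In all, edgeR called 257 of 15128 genes, 135 higher and 122 lower in the deep sublayer, and 1844 genes had an unadjusted p under 0.05 against 756 by chance. Also leading the higher genes were the nucleosome-binding Hmgn5 (0.95), the proteoglycan Spock3 (0.57), the chaperones Hsp90aa1 (0.37) and Hsp90ab1 (0.29), the lactate dehydrogenase Ldhb (0.42), Aplp2 of the App family (0.29) and the SNARE protein Snap25 (0.28). The lower genes included the CaMKII inhibitor Camk2n1 (-0.43), Sash1 (-0.43), the adhesion protein Mdga1 (-0.49), Wfs1, a membrane protein of the endoplasmic reticulum (-0.39), the convertase inhibitor Pcsk1n (-0.57), the sodium pump subunit Atp1b2 (-0.42), Vstm2l (-0.92) and the L1-family protein Chl1 (-0.29). The count fell to 167 without 2N mouse 15-131 or Ts2 mouse 15-224 and to 149 without Ts2 mouse 16-178. It was 473 without all doubted libraries, 207 of which were among the 257. Without the mouse block, pairing ignored, it was 45.

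**Figure D4:**
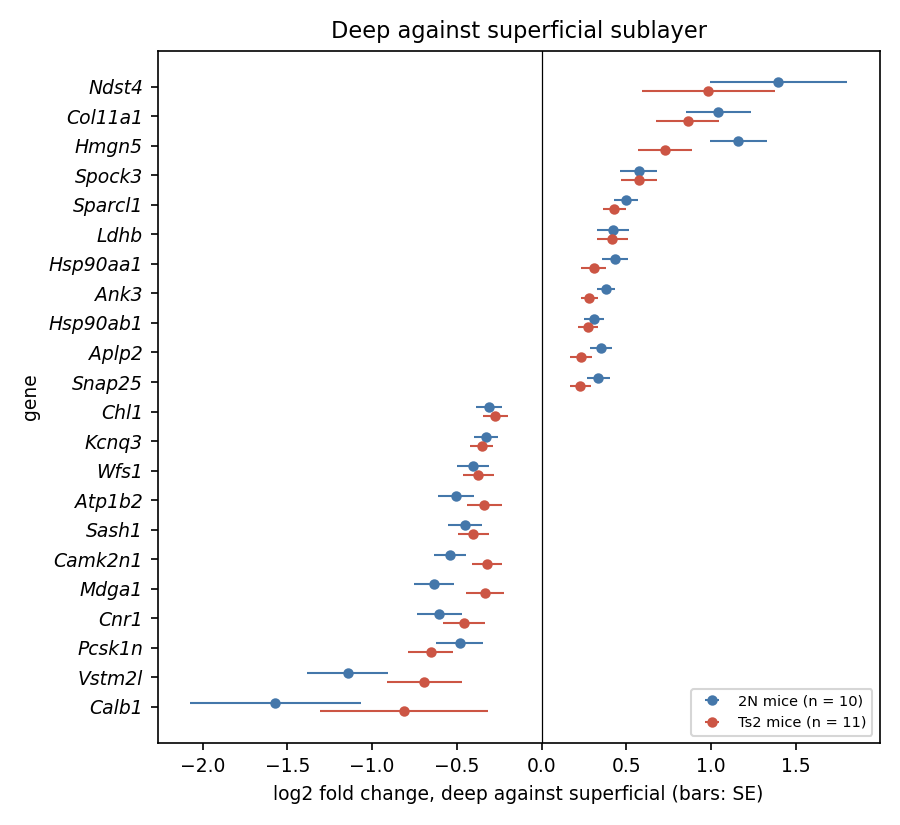
Log2 fold change of the deep against the superficial sublayer for the named genes. The 10 2N and 11 Ts2 mice had separate terms in a single fit, and bars show 1 SE. Genes above 0 are higher in the deep sublayer; Calb1 did not pass the test over both genotypes, and the Ts2 and 2N values of no gene differed by the test of the difference.

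Potassium channel genes were lower in the deep sublayer as a group. Of 47 tested members 13 were higher, 3 passed on the lower side and 1 on the higher side, and 12 and 2 did so adjusted over the list alone (camera adjusted p = 6.5e-05, and adjusted p = 0.0038 with an estimated correlation). Kcnq3 and Kcnh3 (-0.62) were among those on the lower side, and Kcna2 (0.21) was on the higher side. Chaperones were higher in the deep sublayer for 24 of 33 members, 7 of which passed over all genes and 14 adjusted over the list alone, with 1 on the lower side (camera adjusted p = 1.5e-06, and adjusted p = 0.012 with an estimated correlation). Without the doubted libraries this was adjusted p = 0.059 with an estimated correlation. Hspa9 (0.22) and Dnaja1 (0.31) were among them. Deep CA1 markers were higher for 3 of 4 members, and 2 passed over all genes and adjusted over the list alone (camera adjusted p = 5.1e-04, and adjusted p = 0.015 with an estimated correlation).

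Nuclear genes of oxidative phosphorylation were higher in the deep sublayer for 63 of 75 members, 4 of which passed over all genes and 18 adjusted over the list alone, such as Ndufa12 (0.49) and Ndufb3 (0.66). Camera gave an adjusted p = 9.3e-09, and adjusted p = 0.064 with an estimated correlation. Cytoskeleton and axon genes (6 passed, 12 adjusted over the list alone) included the kinesins Kif5a (0.29) and Kif5b (0.34), with camera adjusted p = 1.8e-06, and adjusted p = 0.054 with an estimated correlation. Presynaptic vesicle genes (5 passed, all higher, with 11 higher and 6 lower adjusted over the list alone) included Syt1 (0.20) and Nsf (0.19), with camera adjusted p = 4.4e-04, and adjusted p = 0.094 with an estimated correlation. Postsynaptic scaffolds were lower as a group, with 7 of 31 members higher, 4 passing on the lower side and 1 on the higher, and 9 and 1 adjusted over the list alone, such as Dlgap3 (-0.51) and Nrxn2 (-0.34). Camera gave an adjusted p = 7.2e-06, and adjusted p = 0.078 with an estimated correlation. Cytosolic ribosomal proteins, mitochondrially encoded genes and the ubiquitin-proteasome system were also higher by camera (adjusted p = 1.7e-05, 2.3e-04 and 3.7e-04), with adjusted p = 0.11, 0.16 and 0.064 with an estimated correlation. Of their members 1, 1 and 2 passed over all genes, and 6, 1 and 2 adjusted over the list alone. Signalling genes of MAPK, PI3K and mTOR, CA1 pyramidal markers, calcium and calmodulin genes and superficial CA1 markers were lower (adjusted p = 0.0012, 0.0026, 0.015 and 0.028), with adjusted p = 0.062, 0.078, 0.14 and 0.078 with an estimated correlation. On the lower side 0, 1, 4 and 0 of their members passed over all genes, and 0, 3, 12 and 2 adjusted over the list alone. On the higher side these were 0, 1, 1 and 0, with Neurod6 (0.23) and Calm2 (0.26), and 0, 2, 7 and 0. Without the doubted libraries mitochondrially encoded genes and calcium and calmodulin genes each passed with adjusted p = 0.012 with an estimated correlation. The other lists did not pass, with camera adjusted p from 0.052 for CA3 and CA2 markers to 0.97 for the chromosome 17 segment. Without the doubted libraries interneuron and astrocyte markers passed as higher in deep (camera adjusted p = 0.027 and 0.041). With an estimated correlation these were adjusted p = 0.29 and 0.44.

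Cell type scores give the tissue around these neurons. The CA1 pyramidal score was 6.84 in the deep and 7.09 in the superficial sublayer, higher in deep in 5 of 21 mice (paired permutation test, adjusted p = 0.036). Sst, the interneuron peptide somatostatin, was higher in the deep sublayer (edgeR adjusted p = 0.0069), at 77.8 ± 52.5 CPM (SD, n = 21) against 20.1 ± 13.5 CPM (SD, n = 21). Interneuron markers as a list were split, with 10 of 16 members higher in deep (camera adjusted p = 0.15). Over all genes 1 member passed as higher, Sst, and 1 as lower, Cnr1. The interneuron score was higher in deep than in whole-layer libraries in 21 of 22 mice (difference of 0.568, permutation adjusted p = 0.00033), and the oligodendrocyte score was higher than in the whole layer by 0.598 in the deep (adjusted p = 0.0076) and 0.622 in the superficial sublayer (adjusted p = 0.037), in permutation tests over 22 mice. The identical file of mouse 15-50 stands as deep in the tests of deep against whole. It stands as superficial in the test of superficial against whole. The whole layer came from rostral and the sublayers from distal CA1, and their libraries differed in depth. These tests also include the shallowest library, a whole-layer 2N library of 0.74 M counts. Without that library the mean whole-layer oligodendrocyte score of 2N mice was 2.77, against 2.37 with it. How far the differences from the whole layer rest on position, depth or that library was not tested.

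Within genotypes, 77 genes differed between the sublayers in 10 2N mice, 44 higher and 33 lower in deep, and 6 in 11 Ts2 mice, 3 in each direction. These counts do not show a difference between genotypes, since the direct test called 0 genes. The 2N count ranged from 28 without 2N mouse 16-257 to 143 without Ts2 mouse 16-319. It was 33 without 2N mouse 15-131, 15-223 or 16-208, 39 without 15-71, 32 without 16-268, 30 without 15-49, 124 without 15-75 and 128 without 16-04. The Ts2 count was 1 without Ts2 mouse 15-51, 2 without 15-224, 3 without 16-179 and 10 without 16-207.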

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

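No called value of a named gene turned to the other direction under the alternatives run. Among gene lists, nuclear genes of oxidative phosphorylation in the whole layer passed as higher in batch 1 (camera adjusted p = 0.0029) and as lower in batch 2 (3.3e-05), and did not pass over all mice (0.77). Among named genes, 2014 values kept their side of the threshold, 136 newly passed, 91 no longer passed and 15 moved. Leaving out single mice kept 880 and ended 89. For the counts below, the cause was not tested unless it is given. The alternatives that leave out doubted libraries were chosen after seeing the data. The series tables were not run as a source, since they hold the same values.

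In the whole layer edgeR called 1 gene, which is trisomic. The counts of all genes and of trisomic genes were 40 and 18 with DESeq2, 99 and 53 with limma-voom and quality weights, and 29 and 24 in a single limma-voom fit of all 66 libraries. They were 0 and 0 with upper-quartile scaling, which moved the all-gene median by -0.122, and 0 and 0 without a filter, in batch 1 alone and in batch 2 alone, where fewer mice were tested. A surrogate variable gave 2392 and 72, with 2134 genes higher and 258 lower, and moved the all-gene median by 0.441. Without the libraries under 16000 detected genes, and without all doubted libraries, they were 25 and 18. Leaving out single mice gave 0 to 25 genes and 0 to 18 trisomic genes.

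In the deep sublayer the counts were 21 and 17. DESeq2 gave 48 and 27, and limma-voom with quality weights 57 and 41. Batch 1 alone gave 1 and 1 and batch 2 alone 4 and 4, with fewer mice. Leaving out single mice gave 17 to 23 genes and 15 to 20 trisomic genes.

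In the superficial sublayer the counts were 3 and 3. DESeq2 gave 11 and 7, limma-voom with quality weights 28 and 22, and the single fit of all 66 libraries 8 and 7. No filter gave 5 genes, no batch term 0 and 0, batch 2 alone 0 and 0, and an adjusted p under 0.10 gave 6 and 6. Without the 2 libraries whose dosage goes against their genotype the counts were 16 and 14, and without all doubted libraries 11 and 10. Leaving out single mice gave 2 to 10 genes and 2 to 9 trisomic genes.

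Genes called the same way in all 3 captures numbered 1. There were 2 with DESeq2 and 7 without all doubted libraries, and 0 without a filter, without a batch term, in batch 1 alone, in batch 2 alone and with trisomic genes left out.

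Between the sublayers 257 genes differed over both genotypes, 77 in 2N and 6 in Ts2. Without a filter the counts were 399, 228 and 93, at an adjusted p under 0.10 they were 479, 172 and 17, and without the mouse block, which ignores the pairing, 45, 14 and 3. Without all doubted libraries they were 473, 140 and 19. Without the libraries under 16000 detected genes both genotypes gave 388 and 2N gave 166. Batch 2 alone gave 106 and, in 2N, 21, and batch 1 alone gave 50 in Ts2. With the identical libraries of mouse 15-50 included 2N gave 35. In Ts2, limma-voom with duplicateCorrelation gave 14, and leaving out the 2 libraries against their genotype gave 10. Leaving out single mice gave 149 to 370 over both genotypes, 28 to 143 in 2N and 1 to 10 in Ts2.

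For a genotype effect that differs between captures, edgeR gave 0 genes in each test, and leaving out single mice gave 0 to 0. Without a filter there were 39 for deep against superficial, 11 for deep against whole and 8 for superficial against whole, and a mean CPM of 5 or more gave 1 for superficial against whole. Of the gene lists between genotypes other than the trisomic segments, camera called 23, camera with an estimated correlation 1 and fry 2. The shallowest library, at 0.74 M counts, was the single library whose removal moved the whole-layer count most, to 25.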

Other observations

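Summing the counts of the 3 captures of each mouse, a test chosen after seeing the data, gave a single profile per mouse. The identical file of mouse 15-50 was counted once. Deeper libraries weigh more in such a sum, so the mix of captures differed between mice. The whole layer of 2N mouse 16-268, for example, added only 0.74 M counts. How far this mix moved the calls was not tested. Outside the segments Rfx5, a transcription factor of MHC class II genes, fell by a log2 change of -0.97 ± 0.15 (SE), from 15.1 ± 3.2 CPM (SD, n = 11) to 7.72 ± 2.06 CPM (SD, n = 11), with 0 of 11 Ts2 mice above the 2N mean of their batch (edgeR adjusted p = 0.0010). Col4a1, a basement membrane collagen, rose by 0.67 ± 0.11 (SE, 11 of 11 mice, adjusted p = 0.0024). Also rising were the retinaldehyde dehydrogenase Aldh1a1 (0.82, adjusted p = 0.016), the prostaglandin D synthase Ptgds (0.99, 0.028), the focal adhesion protein Parva (0.60, 0.028) and the matrix protein Crtac1 (0.73, 0.037), each in 11 of 11 mice. The actin crosslinker Flna (-0.63, adjusted p = 0.011), the serotonin receptor Htr4 (-0.73, 0.026), Nap1l5 (-0.47, 0.028), the uncoupling protein Ucp2 (-2.11, 0.033) and the adhesion molecule Cntn4 (-0.58, 0.047) fell, each with 0 of 11 mice above the 2N mean. These genes were named after their values were seen.

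In all, 44 of 19067 genes were called, 33 of them trisomic, and the median fold of trisomic genes was 1.421. Without the doubted libraries 50 genes were called, 38 of them trisomic, with 7 others that rose and 5 that fell. In that run mouse 16-268 was represented by its superficial library alone, and mice 15-50 and 16-319 by their whole-layer library alone. Aldh1a1 (adjusted p = 0.51), Crtac1 (0.11) and Nap1l5 (0.087) then no longer passed, and 4 genes that rose did: Traf3, an adaptor of immune receptors on chromosome 12 (0.57, adjusted p = 0.0094), the collagen Col4a2 (0.63, 0.011), the scaffold Magi3 (0.66, 0.015) and the axonal guidance protein Dpysl3 (0.63, 0.043). The 11 called genes outside the segments compare with a highest count of 0 in the other 49 of 50 splits of the mice. So 1 of 50 splits gave as many, the smallest share that 50 splits can give. Chance is thus unlikely for the count, though the summed test was chosen after seeing the data and single genes depend on the libraries kept.

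Other splits of the mice, with the real split counted, were tested for each count. In the whole layer 1 of 50 splits gave as many genes as the real 1 (highest other 0) and 1 gave as many trisomic genes over the list alone as the real 33 (highest other 0). In the deep sublayer it was 1 of 50 for 21 genes (highest other 0) and 1 for 49 trisomic genes (highest other 7). In the superficial sublayer it was 1 of 50 for 3 genes (highest other 0) and 1 for 35 trisomic genes (highest other 3). For the gene shared by all 3 captures it was 1 of 50 (real value 1, highest other 0). Between the sublayers 1 of 24 splits gave as many as the real 257 genes (highest other 0), 1 as many as the 77 in 2N (highest other 2) and 1 as many as the 6 in Ts2 (highest other 0). These are the smallest shares that 50 or 24 splits can give, and they are not adjusted over the counts tested. Chance is thus unlikely for each count taken by itself. For the genotype counts this says little about genes outside the segments. Of the 21 deep calls 17 are trisomic, as are all 3 superficial calls and the whole-layer call. Permuted labels mix the gene copy numbers, so fewer trisomic calls in other splits follow from the design. The 4 deep calls outside the segments were not counted separately over the splits. The whole-layer count is the single call of Synj1, which ended without any of several single mice. For the 3 tests of a differing genotype effect, 12 of 12 splits reached the real value of 0 (highest other 0). Any split reaches a count of 0, so these splits cannot decide, and 12 splits are also too few for a share under 0.05. Outside the segments 16 genes had an unadjusted p under 0.05 in the same direction in all 3 captures, 9 higher and 7 lower in Ts2, and 8 of 50 splits gave as many, so chance cannot be excluded. The highest other split gave 94, several times the real count, which points to a structure of the samples whose cause was not tested. The identical file of mouse 15-50 counts in both sublayers here, under real and permuted labels.

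The weighings below concern patterns seen in these data, and the tests of the pair difference, of low depth and of the oligodendrocyte markers were chosen after the result was seen. The superficial libraries labelled as Ts2 mouse 16-207 and 2N mouse 16-208 had dosages of 0.051 and 0.563. Low depth is argued against, since the poorer of the 2 has 17133 detected genes. A swap of the 2 libraries may explain the pattern: the difference between these 2 mice correlated at -0.209 between the superficial and deep sublayers, the lowest of 45 pairs in batch 2 (next lowest 0.3). The planned test per library did not decide, with 1 of 2 libraries closer to the other mouse (own minus other mouse -0.25 and 0.03). No biological explanation was tested.

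Oligodendrocyte markers were higher in Ts2 in the deep sublayer. A lower share of CA1 neurons that raised the markers of every other type alike would leave little excess of oligodendrocyte markers over the others. Oligodendrocyte markers exceeded the mean of the other types by 0.81 more in Ts2 than in 2N (permutation p = 0.00074). Without the doubted libraries this was 0.567 (exact permutation p = 0.0054). It was 1.056 in batch 1 (exact permutation p = 0.0043) and 0.515 in batch 2 (exact permutation p = 0.12). The list was singled out because it rose, which favours an excess in advance, so these p cannot weigh the explanation. The oligodendrocyte score alone differed by 0.674, since that mean includes interneuron and precursor markers, which were mostly lower in Ts2. Markers that fall are not what this explanation gives, but no test independent of the choice of list was run. Captures with more oligodendrocytes but no more of the other types are not covered by this test. Whether the difference is carried by batch 1 stays open, since it was 0.929 there (exact permutation p = 0.0065) and 0.367 in batch 2 (exact permutation p = 0.21). More oligodendrocyte RNA in the captures or higher expression per cell may each underlie it, and these data do not separate them.

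Chromosome 7 genes near Ucp2 were among the smallest p outside the segments. Whether a linked block of genes differs between the genotype groups was tested: 6 of 98 genes around Ucp2 had an unadjusted p under 0.05, against a median of 5 and a highest count of 20 in 176 other windows. In 82 of those windows the count was as high, so the test does not decide. No biological explanation was tested.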
